A study of Mus musculus with 8 samples.

How the data were processed

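Total RNA of mouse skeletal muscle at postnatal day 0 and day 65, 4 samples per age, was depleted of ribosomal RNA, copied into Cy3-labelled cRNA with random primers and hybridised to 1-colour Agilent arrays, per the labels' protocols. The arrays were read with Agilent Feature Extraction 11.0.1.1, per the file headers, and the array's grid was built on mm9. The deposited scanner files give, for each spot, an intensity after background subtraction and detrending, the median brightness of the spot and of its local background, and flags of 0 or 1 for spots well above background, saturated or outlying. Whether the software applied multiplicative detrending, a smooth correction across the array surface, was judged from the spot values. The ratio of processed to background-subtracted signal over spots well above background varied on 5 arrays. It did not vary on D0 replicates 2 and 3 and D65 replicate 2. The correction had an SD of 0.07 to 0.13 on the log2 scale where it was applied. The authors also deposited a table of normalized intensity on a linear scale for 14529 probes, with the steps behind it not given in the sources used here.

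The main values were log2 of the processed signal minus the 75th percentile of each array over all probes, as more than 50% of the probes were well above background on every array. Control spots, 20 negative control probes and spots marked as outliers were left out, spots of a probe were averaged, and no probe was saturated. A probe was kept where it was well above background on all 4 arrays of at least 1 age. The ages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over 34948 kept probes. A probe counted as changed at an adjusted p under 0.05 and an absolute log2 difference of at least 1. Summaries were computed in Python with numpy, pandas and scipy, with permutation tests of 10000 draws and bootstrap intervals of 1000 draws, all two-sided. The limma step was tested on simulated data with the spread of these 34948 probes. It recovered 39 of 100 probes changed by 1.5 on the log2 scale and 70 of 100 changed by 2, with 8 false calls. The simulation changed far fewer probes than the 7739 called in the data. Its adjustment was therefore stricter, so these shares do not give the power of the real fit.

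RefSeq accessions were paired with current symbols through a gene table of assembly GRCm38.p6, whose coordinates were not used because the array grid follows mm9. Of 123 probes with a RefSeq accession, 116 matched. A gene with several probes was represented by the brightest over the 8 arrays. The named genes followed a rule set before the data were examined: the coding genes, up to 8 each way, and noncoding genes, up to 6 each way, with the largest changes among those well above background on all 8 arrays whose ages did not overlap, genes with a bound, and members of fixed lists. The bound divides the mean of the brighter age by the mean, per array, of the dimmer probe or the lowest signal well above background, whichever is higher. Noncoding identifiers were limited to 2 each way. Reference genes with 20 spots, Gm6710 and the ultraconserved probes were added after their values were seen.

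The 28 gene lists fixed in advance, which hold 416 members, could not be tested as groups. Only 3 members have a named probe, Gapdh in the glycolysis list, Rpl13a in the ribosomal list and B2m in the antigen presentation list. Of these Rpl13a fell and the others were not called. None of Xist, Ddx3y, Eif2s3y, Kdm5d and Uty has a named probe, so the sex of the samples was not checked. Probes for other Y-linked genes differed between arrays and were not used to assign sex. The pairing of noncoding genes with neighbouring coding genes was not run, since the lincRNA probes carry no gene name. The alternatives changed the background correction, scaling, filter, replicates, weights and thresholds. The mean brightness of spots was not used, and the normexp alternative with an offset of 50 took the median brightness instead. Undoing the multiplicative detrending, the value-table counts and the shift of the lincRNA classes were added after seeing the data.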

Results

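Skeletal muscle of ICR mice, an outbred laboratory strain, was compared at birth (postnatal day 0, D0) and in the young adult (postnatal day 65, D65), with 4 arrays per age. The study set out to find long noncoding RNAs whose level differs between these ages. Each 1-colour array measured labelled RNA of a muscle sample with 59709 probes after control spots were set aside. The probes lie in lincRNA exons (lincRNAs are long transcripts between genes with no known protein), in ultraconserved genome regions, in cDNA and expressed-tag sequences, in a few RefSeq transcripts and, for 51842 probes, under a vendor identifier that no table used here pairs with a gene. At D0, 67.1%, 67.7%, 68.4% and 63.1% of the probes were well above background on replicates 1 to 4. At D65 the shares were 52.3%, 54.2%, 60.7% and 59.2%. Nothing in the labels says that the 4 samples of an age came from separate animals, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision.

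Among the 71 coding genes with a symbol and a kept probe, the chemokine genes Gm13304, Ccl21b and Ccl21c had the largest rises by D65. CCL21 chemokines guide lymphocytes and dendritic cells into lymphatic vessels and lymph nodes. Gm13304 rose from a log2 level of 0.53 ± 0.57 at D0 to 4.77 ± 0.64 at D65 (SD, n = 4 arrays per age), an 18.9-fold rise. Ccl21b rose 18.5-fold and Ccl21c 9.47-fold. These genes are near-identical copies in the mouse genome, so their probes may read the same transcripts, and which copy changed is uncertain.

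Among the coding genes that fell, Tuba1b, which encodes an alpha-tubulin of the microtubules, had the largest change. Its log2 level fell by 2.22 (SE 0.27), from 8.95 ± 0.51 at D0 to 6.74 ± 0.20 at D65 (SD, n = 4), with a limma adjusted p of 0.000269. Disp1, which encodes a protein that releases Hedgehog ligands from cells, fell by 1.59 (SE 0.37). Hprt, a purine salvage enzyme, fell by 1.55 (SE 0.19). Rpl13a, a protein of the large ribosomal subunit, fell by 1.49 (SE 0.20), and Aida fell by 1.31 (SE 0.22). All 3 probes of Ppp2r3d, named for a regulatory subunit of protein phosphatase 2A, fell, with log2 differences of -1.19, -1.23 and -1.38. After normexp background correction the brightest probe of Ppp2r3d differed by -0.69 with quantile normalization and by -0.56 with the 75th percentile, under the minimum change. Nono, an RNA-binding protein of nuclear paraspeckles, fell by 1.23 (SE 0.33, adjusted p 0.0193). The fall of Nono was not called without D0 replicate 1, 2 or 3, with adjusted p of 0.0546, 0.0543 and 0.0525, where all alternatives ranged from 0.000153 to 0.0546.

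Smaller rises were found for Nlrp4g, of the NOD-like receptor family, and for Gm21953. Nlrp4g rose by 1.47 (SE 0.26) and Gm21953 by 1.27 (SE 0.21) on the log2 scale, with adjusted p of 0.00207 and 0.00169. Gm21953 differed by 0.96 after normexp correction with the 75th percentile, below the minimum change. Gm6710 was called higher at D65 with a log2 difference of 1.01, but the levels of the ages overlapped, and the call was lost without any of 6 of the 8 arrays. It was also lost after normexp correction with the 75th percentile (difference 0.79, adjusted p 0.0527) and with no filter on dim probes (adjusted p 0.0566), where all alternatives ranged from 0.00298 to 0.08. Ldhal6b, a lactate dehydrogenase-like gene, was not well above background on any D65 array, and its level was at least 1.37-fold higher at D0 (adjusted p 0.00241). This call of Ldhal6b was lost after normexp correction, with log2 differences of -0.31 with quantile normalization and 0.10 with the 75th percentile, the latter in the opposite direction. Of the 71 coding genes with a symbol and a kept probe, 6 rose, 9 fell and 56 were not called.

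**Figure D1:**
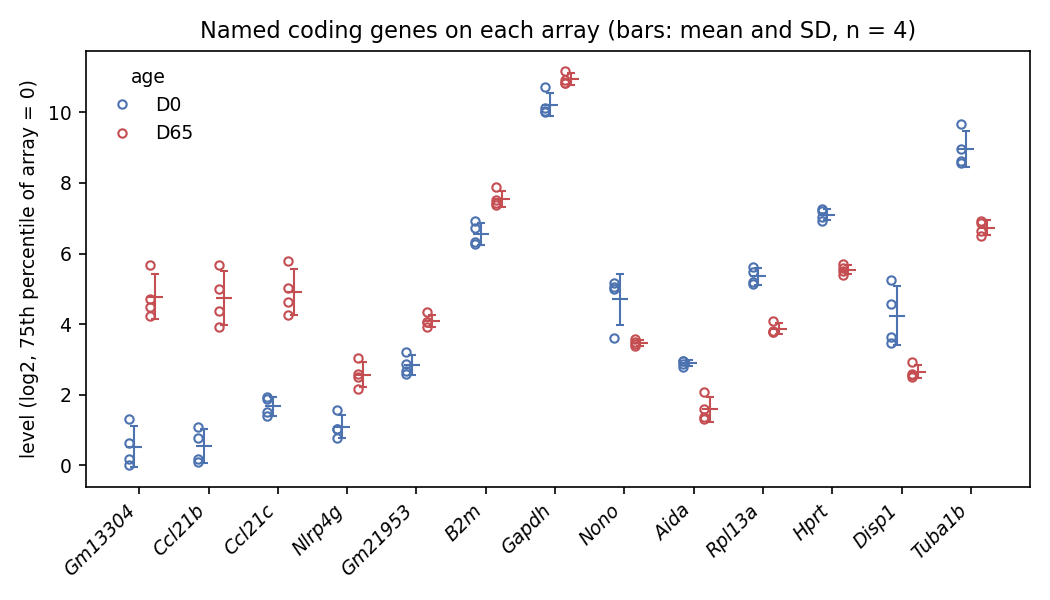
Log2 levels of 13 coding genes (vertical axis, with the 75th percentile of each array at 0) on the 4 D0 arrays (blue circles) and the 4 D65 arrays (red circles), with mean and SD as bars. The D65 arrays of Gm13304 lie between 4.23 and 5.68, above the D0 arrays at 0.01 to 1.30, and for Tuba1b every D65 array lies below every D0 array.

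The array carries 15 genes with 20 spots each, most of them common reference genes. Of these, 6 fell and 0 rose. They are Tuba1b, Hprt, Rpl13a, Nono, Actb and Ldhal6b, the last of which turned direction after normexp correction with the 75th percentile. Actb, which encodes cytoplasmic actin, fell by 1.13 (SE 0.34, adjusted p 0.031), though D0 replicate 4 at 5.47 lay within the D65 values, and the call was lost without any of the 7 other arrays. It was also lost under quantile normalization, after normexp with quantile normalization and with no filter on dim probes. The adjusted p were 0.0704, 0.0693 and 0.0583, where all alternatives of Actb ranged from 0.00079 to 0.0805. For 5 more genes the adjusted p was under 0.05 and the change stayed below the minimum. This count depends on single arrays. Of B2m, Tfrc, Gusb, Ppia and Gapdh, 2, 3 and 2 passed that limit without D0 replicates 1, 2 and 3, and 2, 1, 1 and 1 without D65 replicates 1 to 4. With no filter on dim probes 1 passed and with replicate number as a block 2. B2m passed in every alternative run. B2m, the light chain of MHC class I molecules, stood 0.98 higher at D65 (SE 0.23) and Tfrc, the transferrin receptor, 0.71 higher (SE 0.23). Gusb, a lysosomal glucuronidase, stood at -0.91 (SE 0.26) and Ppia, a prolyl isomerase, at -0.67 (SE 0.22). Gusb passed the minimum change at -1.03 after normexp with the 75th percentile and without D0 replicate 1, and at -1.04 without D0 replicate 2. Tbp stood at -0.65 (SE 0.37) and was not called, but it was called lower, at -1.03, without D0 replicate 4. Gapdh, a glycolytic enzyme, stood 0.72 higher (SE 0.22), but its difference was 0.03 after quantile normalization and -0.01 after normexp with quantile normalization. The difference of B2m passed the minimum change under several settings and reached 1.11 after normexp with quantile normalization.

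Of the lincRNA exon probes kept, 193 of 1774 were higher and 159 were lower at D65. The lincRNA probe MM9LINCRNAEXON10415-_P1 rose 33.9-fold, from 1.49 ± 0.15 to 6.57 ± 0.38 (SD, n = 4), and MM9LINCRNAEXON11268+_P1 rose 13.9-fold, a log2 difference of 3.80 that was 3.14 after normexp correction with the 75th percentile. MM9LINCRNAEXON10021-_P1 fell from 2.89 ± 0.24 to -1.83 ± 0.50 (SD, n = 4), and MM9LINCRNAEXON11730+_P1 fell from 5.27 ± 0.61 to 0.79 ± 0.12. After normexp correction the difference of MM9LINCRNAEXON10021-_P1 moved from -4.73 to -3.29 with quantile normalization and to -3.32 with the 75th percentile. The files do not pair these identifiers with gene names. The long noncoding RNA 4930526I15Rik fell on both of its probes, by 1.06 and 1.07. The call of its brighter probe was lost in 7 alternatives. The differences were -0.94 under quantile normalization, -0.88 after normexp with quantile normalization and -0.95 with the 75th percentile over probes well above background on all arrays. They were -0.93 with the deposited series values, -0.92 with array weights, -0.82 without D0 replicate 4 and -0.98 without D65 replicate 3.

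Most probes for human-derived lincRNAs and mouse lincRNAs, 567 of 651, were not called, and of the 84 that changed 80 were higher at D65. Of 410 human-derived lincRNA probes, 53 were higher and 4 lower at D65, and of 241 mouse lincRNA probes 27 were higher and 0 lower. The median log2 difference over the 651 probes of both classes was 0.34, against 0.06 over all kept probes. This excess of 0.28 was 0.12 after normexp correction with quantile normalization and 0.35 with no filter on dim probes, where the classes had 1908 probes. Vendor-identifier probes drawn at matching signal levels gave a median of 0.07, with the central 95% of 10000 draws between -0.00087 and 0.13, and the permutation p was 0.0001, the smallest these draws can give. The draws treat probes as independent, which they are not, so this p is likely too small. The grouping of both classes was chosen after the class counts were seen, so a higher median was likely beforehand. These probes had low levels, with medians of -1.71 at D0 and -1.20 at D65.

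Ultraconserved regions, stretches of genome kept nearly identical among mammals, changed in both directions. Of 311 kept probes, 21 were higher and 27 lower at D65. The following were chosen after their values were seen. The probe uc.403+ rose 36.5-fold, from -1.89 ± 1.00 at D0 to 3.30 ± 0.65 at D65 (SD, n = 4), a log2 difference of 5.19 that was 3.95 and 3.94 after normexp correction with quantile normalization and with the 75th percentile. The probes uc.133- and uc.414- rose 4.13-fold and 3.85-fold. The probe uc.101- fell by 2.71 (SE 0.36) and uc.256+ by 2.38 (SE 0.58). After normexp correction uc.101- differed by -1.95 with the 75th percentile, and uc.256+ by -1.33. Without D0 replicate 3, uc.256+ differed by -3.00. The probe uc.46- fell by 2.93 (SE 0.87), but its D0 arrays ranged from 2.38 to 6.38, and the call was lost without D0 replicate 1 or 2 (adjusted p 0.0665 and 0.0703, differences of -2.29 and -2.30) and without any D65 array. It was also lost with no filter on dim probes (adjusted p 0.0508), where all alternatives ranged from 0.000433 to 0.0703. The difference of uc.46- was -3.62 without D0 replicate 4 and -4.10 with array weights.

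**Figure D2:**
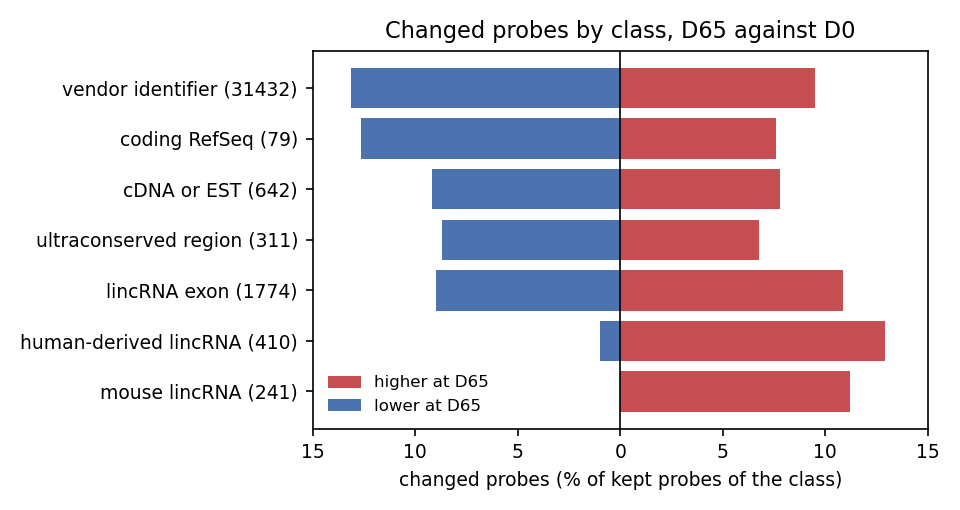
Share of kept probes of each class (horizontal axis, percent) that were higher at D65 (red, to the right) or lower at D65 (blue, to the left), with the number of kept probes in parentheses. Mouse lincRNA probes were higher in 11.2% and lower in 0%, and vendor-identifier probes were higher in 9.51% and lower in 13.1%.

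Over the whole array, 34948 probes were well above background on all 4 arrays of at least 1 age. Of these, 7739 changed between the ages (limma, adjusted p under 0.05 and a log2 difference of at least 1), 3344 higher and 4395 lower at D65. Among changed probes well above background on all 8 arrays, the 2798 lower had a median fold of 3.12 and the 2881 higher a median fold of 2.60. Scaling to the 75th percentile over probes well above background on all arrays gave 4200 higher and 3866 lower, and probes well above background on all 8 arrays gave 2926 higher and 2832 lower. After normexp correction 4475 probes changed with the 75th percentile and 4241 with quantile normalization. The values of the ages did not overlap for 11004 kept probes, or 31.5%. Chance gives 2.86% for probes kept without regard to age. The kept probes include some that passed the filter through 1 age only, which favours a difference, so the 2 shares are not strictly comparable. Of the probes well above background on all 4 D0 arrays, 1288 were so on no D65 array, and 51 showed the opposite. The bright corner control spots were also dimmer on the D65 arrays, with medians of 7563 to 10462 against 11193 to 16918 at D0.

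The authors' value table lists 14529 of the 28106 probes that were well above background on all 8 arrays. It lists all such lincRNA and ultraconserved probes and none of the 68 coding RefSeq probes. Of its probes, 1562 were higher and 1193 lower at D65, against 1319 higher and 1605 lower among the 13577 such probes outside it. The odds of a rise against a fall were 1.46 times as high inside the table, with signal level matched in 10 bins (permutation p 0.0001, the smallest the draws can give). Probes are not independent replicates, so this p is likely too small. With normexp correction and the 75th percentile the table's probes counted 760 higher and 1062 lower, and with the 75th percentile over probes well above background on all arrays 2004 higher and 1023 lower.

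The shares of noncoding and coding probes that changed did not differ detectably. Of 2429 kept noncoding probes 439 changed, 273 higher and 166 lower, and of 79 coding RefSeq probes 16 changed. The 79 include the 15 genes with 20 spots each, 6 of which were called, and the noncoding probes have no such repeats. The odds ratio with signal level matched was 0.955 (permutation p 0.886). So few coding probes leave a difference in the shares undetectable unless it is large.

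Changes on opposite strands of a region were weakly correlated. Of 3157 regions with a probe on each strand, 653 had both probes kept. The log2 differences of their strands had a Spearman correlation of 0.0971 across regions, which are not independent replicates (permutation p 0.0139). In 24 regions both strands changed, 15 in the same direction and 9 in opposite directions, and in 194 regions 1 strand changed. The region of uc.12 rose by 1.07 on the plus strand and fell by 2.30 on the minus strand, as named after its values were seen.

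The D0 arrays were on the first row of the slide and the D65 arrays on the second, so row and age cannot be told apart. D0 replicate 4 stood apart from the other D0 arrays, with Spearman correlations of 0.886 to 0.913 across probes against 0.942 to 0.973 among the other 3. With the D65 arrays it correlated at 0.852 to 0.882, the highest being with D65 replicate 1. The other D0 arrays correlated with the D65 arrays at 0.842 to 0.888. Without D0 replicate 4, 9243 probes changed, 4323 higher and 4920 lower.

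**Figure D3:**
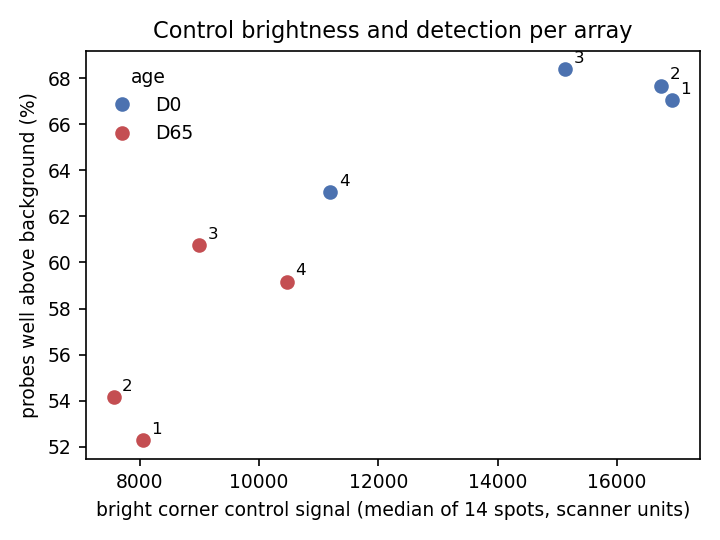
Median signal of the 14 bright corner control spots (horizontal axis, scanner units) and share of probes well above background (vertical axis, percent) for each array, labelled by replicate, with D0 in blue and D65 in red. The D65 arrays lie between 7563 and 10462 on the horizontal axis, below the D0 arrays at 11193 to 16918.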

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

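The tests of D65 RNA in D0 replicate 4, of negative controls and of bright corner spots were chosen after the values they use, or related ones, had been seen. Of 78 groups of 4 arrays tested for an array far from the others, 4 had one, and chance gives about 1 in 20. In 3 of them the array is D0 replicate 4. On that array Nono stood at 3.61, against 4.99 to 5.16 on the other D0 arrays. Tbp stood there at 0.34, against 1.78 to 2.05. Gapdh stood there at 10.71, against 10.02 to 10.13. In the other group, Rpl13a stood at 4.10 on D65 replicate 1, against 3.79 to 3.81 on the other D65 arrays.

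D0 replicate 4 differs from the other D0 arrays across the array. Brightness or scale is argued against as the whole cause, since among the 25% brightest probes, where noise from a dim array is small, its highest Spearman correlation with a D0 array, 0.939, still lay below the lowest among the other 3, 0.949, though closer than the 0.913 and 0.942 over all kept probes. For D65 RNA in the sample or a wrong age label the evidence was mixed. A first test found that its deviation goes with the age difference, with slopes of 0.16 to 0.25 against -0.25 to 0.02 for the other D0 arrays, and a second, chosen after the first was seen, found that 187 probes at least 8-fold higher at D65 allow a median of 2.73% D65 signal in it (95% interval 1.79 to 4.03), against -0.79%, -0.36% and 3.06% in D0 replicates 1 to 3, which argues against it as the whole cause and leaves a small admixture open. Signal without strand, such as genomic DNA, stays open, as may a difference between animals, which was not tested: the median strand difference on it was 1.79, below the 1.92 to 2.03 of the other D0 arrays with a 95% interval of 1.65 to 1.94 that reaches replicate 3, at 1.92, but not replicates 1 and 2, at 2.03 and 1.96. The brightness of negative control spots had an SD of 548 on D0 replicate 4, against 17 to 21 on the other D0 arrays. It had 54 outlier spots, against 21 to 26. Its 23 probes for Y-linked genes had a median level of 0.11, against -4.33, -4.48 and -2.20 on D0 replicates 1 to 3. The bearing of these values on the cause was not tested.

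Fewer probes were well above background at D65. Brighter background is argued against as the whole cause, since the median brightness of negative control spots overlapped. It was 50 to 63 at D65 and 51.5 to 61 at D0, although the array at 63, D65 replicate 1, had the fewest probes above background. The SD of the brightness of these spots also overlapped, with 13 to 56 at D65 and 17 to 548 at D0. Negative control spots passed as well above background more often on every D0 array (15.3% to 18.4%) than on any D65 array (8.67% to 13.8%). The flag thus passed control spots more readily at D0. Whether this adds to the probes counted there was not tested. Dimmer arrays may account for it, since the bright corner spots gave at most 10462 at D65 and at least 11193 at D0. These medians follow the detrending of some arrays. Before it they were at most 8163 at D65 and at least 8538 at D0, a smaller gap. The SD over the processed spots of an array was 804 to 2487. The 75th percentile signal was 262 to 316 on D0 replicates 1 to 3. On D0 replicate 4 it was 139, below the 149 and 155 of D65 replicates 3 and 4. Yet 63.1% of its probes were well above background, against 60.7% and 59.2%. A larger share of signal in a few probes may also account for the fewer probes, since the 100 brightest held at least 17.7% at D65 and at most 14.7% at D0. Slide row follows age, so these and a biological difference with age stay open, and the 1288 probes seen at D0 alone carry this limit.

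Of 20 negative control probes, which were left out of the probe counts, 2 were well above background on most of their 60 spots on all 8 arrays.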

How the results depend on the processing

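The count of changed probes, 7739, fell to 4241 (1917 higher, 2324 lower; 188 noncoding) after normexp with quantile normalization and to 4475 (1644 higher, 2831 lower; 188 noncoding) after normexp with the 75th percentile; the cause was not tested. The deposited values, with fewer probes, gave 2734 (1634 higher, 1100 lower). They gave 0 changed coding probes against 16, since they include no coding RefSeq probe. A minimum log2 difference of 2 gave 2433 (695 higher, 1738 lower; 106 noncoding, 4 coding), and no minimum gave 5122 higher. Probes well above background on all 8 arrays gave 2832 lower; this filter removes probes that were dim on any array. Value-table probes, counted after seeing the data, gave 884 higher and 773 lower after normexp with quantile normalization, 760 higher after normexp with the 75th percentile, 249 higher and 360 lower with the larger minimum and 2492 higher with none. Leaving out each array gave 6898 to 9243 changed probes, the most without D0 replicate 4. The other planned counts stayed within 1.5 times. The median of all kept probes, 0.06, moved to 0.19 after normexp with the 75th percentile and to 0.18 with the percentile over probes well above background on all arrays. Over the same probes it was 0.04 after normexp with quantile normalization, 0.10 with array weights and 0.11 without D0 replicate 4. Over other sets of probes it was 0.21 with no filter, 0.15 for those well above background on all 8 arrays and 0.20 for the deposited values. Directions are relative to these scalings.

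Undoing the multiplicative detrending, added after seeing the data, gave 7778 changed probes. The odds ratio of noncoding against coding probes ranged from 0.748 to 1.02 with no call. The shift of the lincRNA classes and the odds ratio of the value table, both chosen after seeing the data, kept their direction and call in every setting run, though the shift moved from 0.28 to 0.12 after normexp with quantile normalization and to 0.35 over the larger set of probes without a filter on dim ones. For the 26 named genes that were called, 464 of 504 alternative values kept the call, 39 lost it and 1 turned direction, Ldhal6b at 0.10 after normexp with the 75th percentile. For the 9 that were not, 12 of 171 values were called, and Gapdh turned from 0.72 to -0.01 after normexp with quantile normalization.

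The correlations do not settle whether the replicate numbers pair the samples. The deviations of same-numbered arrays correlated at -0.12, 0.24, 0.28 and -0.13. The highest correlation of all pairs was 0.34, for D0 replicate 4 and D65 replicate 1. Same-numbered arrays also shared a slide column. With replicate number as a block, 7750 probes changed. The set tests of the 28 lists, their alternatives, and the neighbour pairs were not run. Signal over background limits what can be said of dim probes.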

Other observations

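The Y-linked multicopy gene families Ssty2 and Sly, active in sperm development, differed between arrays more than between ages. Of 23 probes for Y-linked genes, 22 were well above background on D0 replicate 3 and 21 on D0 replicate 4, but 11 and 10 on D0 replicates 1 and 2. At D65 the numbers were 7, 20, 16 and 21. The Ssty2 probe stood at -4.84, -4.67, -1.96 and 0.84 on the D0 arrays and at -3.39, -0.89, -2.93 and -1.95 on the D65 arrays.

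The tests of the lincRNA shift were chosen after the class counts were seen, with their outcomes unseen. The counts, 80 higher and 4 lower, came from the same arrays, so a higher median was likely beforehand and the draws are not independent evidence. The median log2 difference of human-derived and mouse lincRNA probes lay above that of the other probes. Their levels at D65 were lower, with a median of -1.20 against -0.52 over all kept probes. The class median of 0.34 lies above the 0.13 that bounds the draws matched on level, so on these arrays the classes differed from vendor probes of the same level. The scanner software's background correction is argued against as the whole cause. After normexp with the 75th percentile the median difference of the classes still lay 0.20 above that of all probes (95% interval 0.18 to 0.23). After normexp with quantile normalization it lay 0.12 above (0.088 to 0.142). Without normexp the shifts were 0.28 with the 75th percentile and 0.25 with quantile normalization. The offset added in normexp also shrinks log2 differences of dim probes. The smaller shifts therefore cannot tell whether a part comes from the scanner software's correction, which stays open. Among value-table probes on all 8 arrays the classes had a median of 0.41 against 0.24 for vendor probes matched on level. Probe design and a difference with age stay open, both untested.

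Chance in how these 8 arrays are divided is argued against as the source of the changed probes, but not excluded. Of the 35 splits of the 8 arrays into 4 and 4, 1, the real one, gave as many as 7739, and the highest of the others gave 1. With 35 splits the smallest possible share is 1 in 35. The other splits mix the ages, which widens the spread within their groups, so their low counts do not measure how many calls chance gives. These splits cannot address a chance difference between the animals or pools behind each age, nor an effect of slide row, which follows age.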
